A study of Mus musculus with 6 samples.

How the data were processed

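RNA from 3 DP-DSC and 3 TP-DSC samples of one mouse dysplastic organoid line was sequenced after polyA selection with a stranded library kit, per the labels' protocols. The deposited files hold, for each sample, 1 raw read count per gene symbol, with no normalization by the authors apparent in the values. The counts were whole numbers whose totals differed between samples. Per the submitters' processing notes, the tools were STAR 2.7.3a, Partek and DESeq2 3.5, with genome build mm10; the roles of the tools are not given in the sources used here, nor is the strand setting of the counting. Genes that overlap or have near-identical copies may therefore have lost or gained reads. Each file ended with a row for reads that fell in no gene and a row for ambiguous reads. These 2 rows were left out of library sizes and tests. Reads in no gene made up 15.4, 15.1 and 14.1% of all reads in DP-DSCs replicates 1, 2 and 3, and 16.2, 20.3 and 19.2% in TP-DSCs replicates 1, 2 and 3. Ambiguous reads made up 1.09 to 1.86%.

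Samples were grouped by the cell subtype label. Replicate numbers follow the order of deposit and pair no samples. The number 3840 or 4140 in the library names was read as a sequencing submission and treated as a technical batch; the labels do not say what it marks. To check only for a library deposited in duplicate, replicates of a group were compared with a chi-square over genes. It ranged from 112.2 to 306.1 per degree of freedom, so all libraries were counted separately; separately made libraries always exceed read-counting noise, so this says nothing of how alike the replicates are.

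Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by the trimmed mean of M values (TMM), and groups were compared with the quasi-likelihood F test with group as the only term and Benjamini-Hochberg adjustment at 0.05. Positive log2 fold changes mean higher in TP-DSCs. The standard error was taken as the log2 fold change divided by the square root of F. CPM values of named genes are TMM-scaled, and those of markers of other cell types are scaled by the library's gene reads alone. Differences within a submission are differences of mean log2 CPM with a prior count of 2. Gene lists (38 lists with 985 genes, of which 949 had a row in the files) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, for the 31 lists with 5 or more tested genes, two-sided, with Benjamini-Hochberg adjustment over the lists. The same test with an estimated correlation stands beside it. Camera compares the genes of a list with all other tested genes, so its direction is relative to those and not to 0. For genes without reads in TP-DSCs, fold changes are given against a floor of 3 counts over the 3 libraries; with such genes at that bound, no list median given here changed at the printed precision.

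The rule for named genes, fixed before the data were examined, took up to 12 genes per direction with the largest change among genes past the threshold, with a mean log2 CPM of at least 2, separated groups and no clone or predicted name. None passed, so the rule's second part applied, the 10 genes with the smallest p in each direction, said not to pass. It also took the sort and epithelial surface markers, up to 4 members per described list by p, and up to 3 per list of other cell types by mean CPM. Some genes that the rule takes are not reported here. Lgr5, Cdk1, Top2a, Pcna, H2-K1, Rn45s and the lysosomal genes fall outside the rule and were chosen after their values were seen, as were the genes named with the abundance, naming and separation criteria kept.

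On simulated counts for the 11925 genes, drawn with the real means, library sizes and gene-wise dispersions and with 200 changed genes, edgeR recovered 2.0% of genes changed 2-fold and 33.2% of those changed 4-fold with 2.4 false calls on average over 5 simulations. DESeq2 1.42.0 recovered 19.6 and 63.6% with 95.2 false calls. A simulated list of 36 genes shifted by 0.7 (log2) was called by camera in 20 of 20 simulations and an unshifted list in 0 of 20, where simulated genes vary independently. The biological coefficient of variation from the common dispersion was 0.75.

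Alternatives were DESeq2 size factors, upper-quartile factors and library size only; DESeq2 (with its independent filtering set for 0.05) and limma-voom as the test; no filter and a mean count of 10; a log2 fold change of at least 1; the submission number as a block; submission 4140 alone; leaving out each library; and, for lists, fry and an estimated correlation. Restricting to genes with reads in all 6 libraries and removing the GC content and transcript length trend of each library were added after seeing the data. Transcript length, GC content and coordinates came from GENCODE M21 (GRCm38, the same assembly as mm10), the longest protein-coding transcript per gene where there was one, matched for 98.4% of 23420 symbols. The random lists, drawn in Python 3.11.15, took each gene from its 50 nearest neighbours, 10000 times.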

Results

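The data compared gene expression between 2 subpopulations of dysplastic stem cells sorted by flow cytometry from Meta4 organoids, a mouse line of dysplastic epithelial organoids. The labels call the subpopulations DP-DSCs and TP-DSCs. Polyadenylated RNA was sequenced from 3 libraries of each. DP and TP are understood here as double and triple positive for surface markers, namely CD133 (gene Prom1) and CD166 (gene Alcam), with the CD44v6 form of CD44 added in TP-DSCs. That reading comes from knowledge of the study and not from the labels. The library names carry the numbers 3840 and 4140, which are read here as sequencing submissions although the labels do not say what they mean. Submission 3840 held 1 library of each group, and submission 4140 held 2 of each. Reads assigned to genes numbered 32594133, 32671039 and 27027919 in DP-DSCs replicates 1, 2 and 3, and 24949764, 17015581 and 31068454 in TP-DSCs replicates 1, 2 and 3. Genes with at least 1 read averaged 13632 ± 1005 (SD, n = 3) in DP-DSCs and 10710 ± 235 (SD, n = 3) in TP-DSCs, with no overlap between the groups (exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 libraries allow). The labels describe the samples as independent but do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

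The first comparison asked whether transcripts of the sort markers differed between the sorted populations. The libraries of the 2 groups overlapped for all 3 of these genes. Cd44 stood at 505 ± 106 CPM (TMM-scaled counts relative to library size; SD, n = 3) in DP-DSCs and 473 ± 61.3 (SD, n = 3) in TP-DSCs. Prom1 stood at 774 ± 151 and 647 ± 84.7 CPM, and Alcam at 312 ± 61.0 and 318 ± 69.0 CPM, in the same order. A gene-level count does not separate the v6 form from other forms of Cd44, so the Cd44 value does not check that gate. The general epithelial genes were abundant in both groups. Epcam, an epithelial adhesion molecule, stood at 959 ± 195 CPM in DP-DSCs and 849 ± 180 in TP-DSCs, and the lowest value of the keratins Krt8 and Krt18 in any library was 2093 CPM (Krt18 in TP-DSCs replicate 3). None of the 8 sort and epithelial surface marker genes passed a false discovery rate of 0.05 in edgeR's quasi-likelihood test, either over all genes or adjusted over the list alone. Cdh1 (E-cadherin) averaged 1081 ± 220 CPM in DP-DSCs and 743 ± 37.1 in TP-DSCs, with an edgeR adjusted p of 0.744 over all genes and 0.164 over the list alone.

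**Figure D1:**
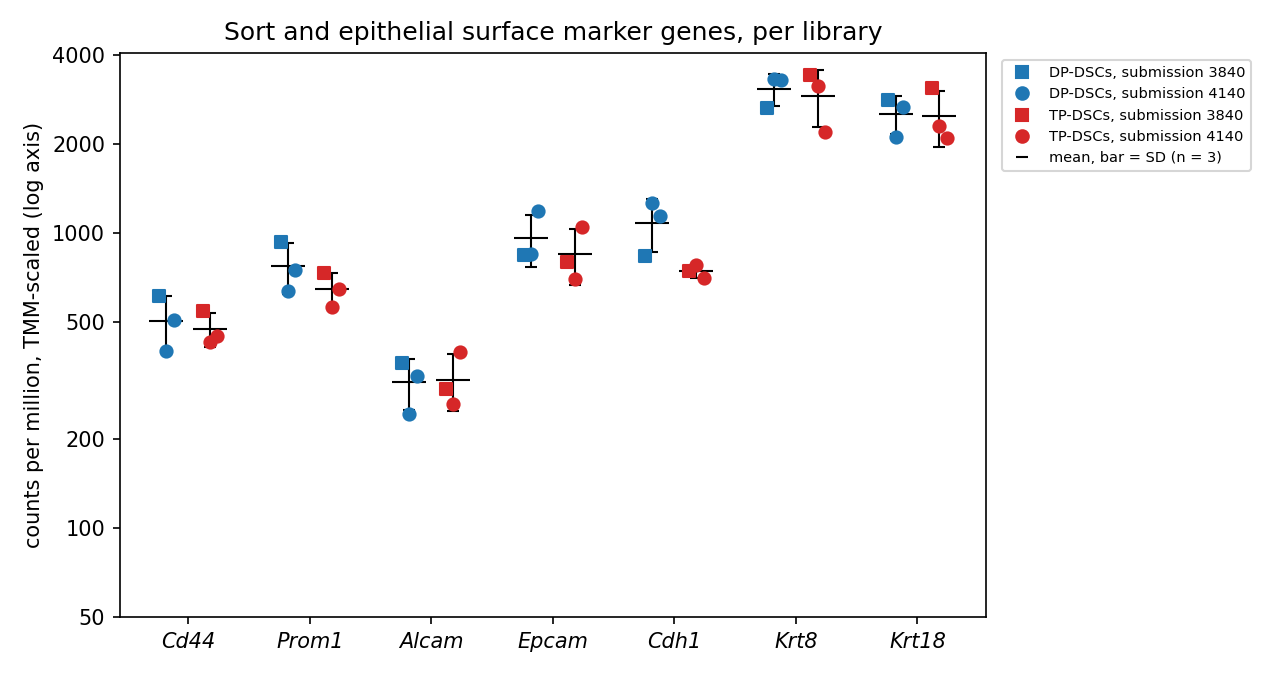
Sort and epithelial surface marker genes per library, in TMM-scaled CPM on a log axis; squares are submission 3840 and circles submission 4140, with the mean and SD of 3 libraries per group. Cd44, Prom1 and Alcam overlap between the groups, while Cdh1 averages 1081 CPM in DP-DSCs and 743 in TP-DSCs.

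The main comparison asked which genes differed between TP-DSCs and DP-DSCs. The genes closest to a call in the upward direction were genes of mitosis. Mki67, the Ki-67 proliferation antigen, averaged 123 ± 15.95 CPM in DP-DSCs and 302 ± 46.6 CPM in TP-DSCs (SD, n = 3 each), a log2 fold change of 1.30 ± 0.20 (SE). The kinetochore genes Cenpf and Cenpe had log2 fold changes of 1.98 ± 0.37 and 1.69 ± 0.32, the condensin subunit Smc4 of 1.33 ± 0.24, and the spindle protein Nusap1 of 1.43 ± 0.34. In the downward direction Tapbp (tapasin, which loads peptide onto MHC class I) averaged 87.6 ± 3.54 CPM in DP-DSCs and 43.2 ± 2.86 in TP-DSCs, a log2 fold change of -1.02 ± 0.19. None of these genes passed the threshold in edgeR, while DESeq2 called all of them (Mki67 with an adjusted p of 5.112e-07 in DESeq2, and from 5.112e-07 to 0.998 over all alternatives). Of 11925 genes tested with edgeR, 0 had an adjusted p under 0.05, the smallest adjusted p being 0.121. At an unadjusted p under 0.05 there were 728 genes, 171 higher and 557 lower in TP-DSCs, where 596 would be expected with no difference at all. Of these 557 lower genes, 387 had no reads in any TP-DSC library, and among genes with reads in all 6 libraries 171 were higher and 143 lower. DESeq2 called 278 genes, 42 higher and 236 lower, and limma-voom called 0 genes with 961 at an unadjusted p under 0.05. Of the 236 genes DESeq2 placed lower, 194 had no reads in any TP-DSC library, and among its calls with reads in all 6 libraries 40 were higher and 23 lower.

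The 10 smallest p-values in each direction, which did not pass in edgeR, gave the genes named next. Upward, Mki67, Smc4, Cenpf, Cenpe and Nusap1 were followed by Pard3b (a cell polarity gene), Klf4 (a transcription factor of epithelial differentiation), Pcca (the alpha subunit of propionyl-CoA carboxylase), Rbbp6 and Kif20b (a mitotic kinesin). Pard3b averaged 14.8 ± 1.76 CPM in DP-DSCs and 39.3 ± 3.52 in TP-DSCs. Klf4 averaged 86.9 ± 9.75 and 148 ± 16.7 CPM, and Kif20b 14.8 ± 2.76 and 48.8 ± 25.4 CPM, in the same order. In each of these 10 genes all 3 TP-DSC libraries lay above all 3 DP-DSC libraries, and DESeq2 called all 10. Downward, the genes were Abtb1, Tapbp, Pcyt1b, Lysmd4, Adamts17, Pdgfrl, Rnu73b, Igfbp2, Snord53 and Gpr157. Of these, 9 had no reads in any TP-DSC library and 6 had a mean log2 CPM under 2. DESeq2 called Abtb1, Tapbp, Pcyt1b and Lysmd4 and not the other 6. Without reads, 3 counts over the TP-DSC libraries allow up to 0.0411 CPM. Against that floor of reads the fold was 288 for Abtb1, 355 for Pcyt1b, 206 for Lysmd4 and 18.1 for Igfbp2 (0.743 ± 0.0453 CPM in DP-DSCs). These are not lower bounds on expression, since reads are not independent molecules. The share of genes without reads gave estimates of 237000, 164000 and 166000 captured molecules in TP-DSCs replicates 1, 2 and 3. That is 105, 104 and 187 reads per molecule, if genes are expressed as in DP-DSCs. A floor of 3 molecules would lie far higher and leave far smaller folds, and none for a gene as scarce as Igfbp2. The TP-DSC libraries held fewer genes with reads (10982, 10571 and 10578) than the DP-DSC libraries (14434, 12504 and 13957).

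With the abundance, naming and separation criteria kept, a choice made after values were seen, the smallest p-values also included Cav2 and Akap9 upward and Pccb, Gpd1, Isyna1, Klhdc3, Osbpl3, Snx17 and Megf6 downward. Pccb, the beta subunit of propionyl-CoA carboxylase, averaged 44.2 ± 6.06 CPM in DP-DSCs and 19.0 ± 0.765 in TP-DSCs, a log2 fold change of -1.22 ± 0.30 (SE). Its partner subunit Pcca averaged 36.4 ± 6.06 CPM in DP-DSCs and 67.7 ± 5.02 in TP-DSCs, a log2 fold change of 0.90 ± 0.23. Gpd1, which makes glycerol 3-phosphate, averaged 112 ± 14.6 and 58.1 ± 13.2 CPM. Isyna1, the inositol 3-phosphate synthase, averaged 124 ± 13.2 and 69.7 ± 13.3 CPM. In all, 480 tested genes had every TP-DSC library above every DP-DSC library and 1059 had every one below. Together they made up 12.9% of tested genes, where 10% is the share chance gives. A gene without reads in TP-DSCs counts as below whenever all 3 DP-DSC libraries have reads. At an unadjusted p under 0.05 in edgeR, 387 lower genes had no reads in any TP-DSC library. The excess over 10% may come from such genes.

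In the annotation of mm10 (GRCm38), Mki67 lies on chromosome 7 from 135689784 to 135716361 and Cenpf on chromosome 1 from 189640606 to 189688086. Cenpe lies on chromosome 3 from 135212537 to 135273611, and Smc4 on the same chromosome from 69004738 to 69034623. Tapbp lies on chromosome 17 from 33915899 to 33929292. Pcca lies on chromosome 14 from 122534324 to 122891100 and Pccb on chromosome 9 from 100982032 to 101034898. Counts are per gene, over its annotated exons as the counting defined them.

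**Figure D2:**
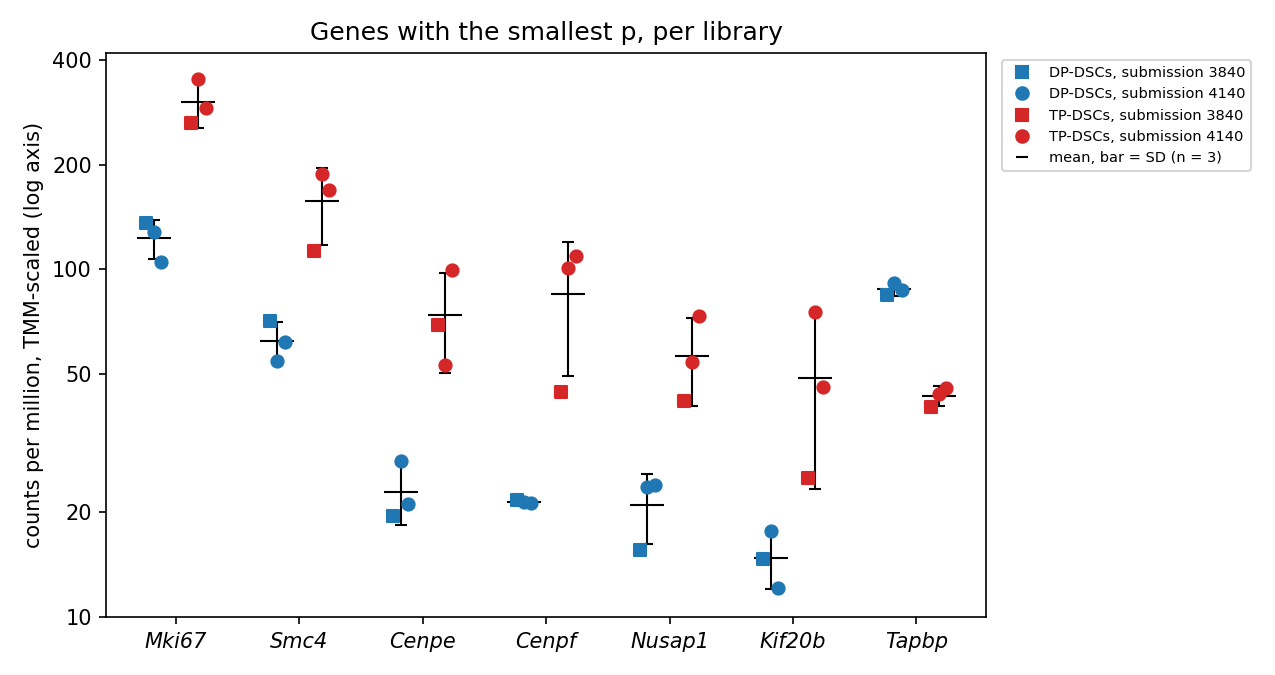
Genes with the smallest p-values per library, in TMM-scaled CPM on a log axis; squares are submission 3840 and circles submission 4140, with the mean and SD of 3 libraries per group. Mki67 averages 123 CPM in DP-DSCs and 302 in TP-DSCs, and Tapbp 87.6 and 43.2.

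The 2 submissions were compared because each held both groups. In the 4 libraries of submission 4140 alone, edgeR called 0 of 12066 genes, with 1473 at an unadjusted p under 0.05, and DESeq2 called 275 genes, 68 higher and 207 lower. Mki67 differed by 1.47 (log2) in submission 4140 and by 0.95 in the single pair of submission 3840, which has no replicate check. Cenpf differed by 2.29 and 1.02, Cenpe by 1.57 and 1.82, and Tapbp by -0.99 and -1.07, in the same order. With the submission number as a block, edgeR again called 0 genes. It also called 0 genes between the submissions, with 1109 at an unadjusted p under 0.05.

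Gene lists written before the data were examined were then compared. The list of G2 and M phase genes was the one furthest above 0. Of its 36 members, all tested, 35 had a positive log2 fold change, the median was 0.70 and 9 had every TP-DSC library above every DP-DSC library. None passed over all genes, and 5 passed adjusted over the list alone: Mki67, Cenpf, Cenpe, Nusap1 and Kif20b. The cyclin-dependent kinase Cdk1 and the topoisomerase Top2a had log2 fold changes of 0.82 and 0.76 without passing. The median was 0.85 in submission 3840 and 0.67 in submission 4140. By library, the median deviation of the list's genes was -0.863, 0.154 and -0.304 in DP-DSCs replicates 1, 2 and 3. In TP-DSCs replicates 1, 2 and 3 it was -0.001, 0.805 and 0.464, so the groups overlapped over all libraries. Within submission 4140 they did not overlap, which 2 against 2 libraries can readily give by chance. Submission 3840, with 1 library of each group, could not show an overlap. In limma's camera test with a preset inter-gene correlation of 0.01, the G2 and M phase list was higher in TP-DSCs relative to the other tested genes (adjusted p = 2.835e-13). This call did not hold with a correlation estimated from the data (adjusted p = 0.904 with an estimated correlation; unadjusted p = 0.0999), nor in fry.

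The S phase list, replication genes such as Pcna and Gmnn, had 24 of 30 members above 0 and a median log2 fold change of 0.50. Gmnn averaged 26.9 ± 7.29 CPM in DP-DSCs and 49.5 ± 15.03 in TP-DSCs, Pola1 21.6 ± 3.73 and 40.2 ± 14.4, and Pcna 186 ± 61.8 and 270 ± 55.7, none of them past the threshold over all genes or adjusted over the list alone. Camera with the preset correlation placed the list higher in TP-DSCs relative to the other tested genes (adjusted p = 8.76e-05, and 0.904 with an estimated correlation). The median was 0.77 in submission 3840 and 0.10 in submission 4140, and without DP-DSCs replicate 1 it was 0.19 with an adjusted p of 0.225. The hypoxia and glycolysis list had 24 of 32 members above 0 and a median of 0.13. It had 0 members past the threshold over all genes or adjusted over the list alone. Camera's adjusted p for this list was 0.00472 with the preset correlation and 0.904 with an estimated one. Over genes with reads in all 6 libraries it was 0.030 with the preset correlation. The hypoxia members with the smallest p were Egln1, an oxygen sensor, with a log2 fold change of 0.56, and Higd1a with 0.56. The hypoxia median was -0.01 in submission 3840 and 0.40 in submission 4140 (0.186 in the edgeR fit of that submission alone), and it turned to -0.22 without DP-DSCs replicate 2 and to -0.04 without TP-DSCs replicate 1. These 3 lists were the only ones of the 31 with 5 or more tested genes to pass with the preset correlation, and 0 passed with an estimated correlation or in fry.

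**Figure D3:**
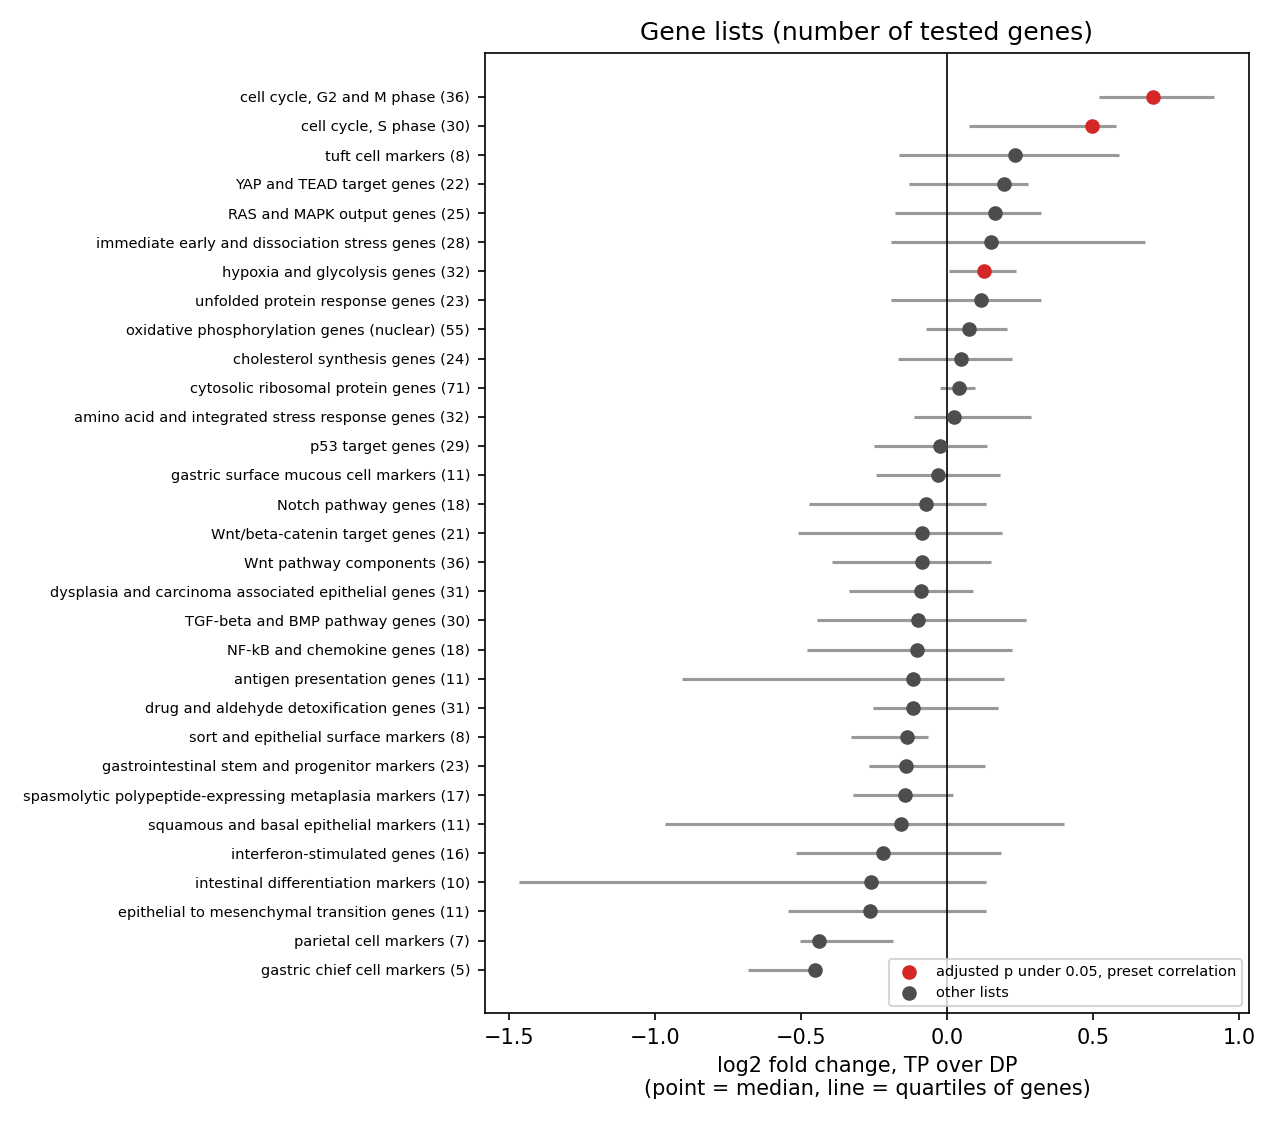
Median log2 fold change (TP-DSCs over DP-DSCs) of the genes of each list with 5 or more tested genes, with lines from the lower to the upper quartile and the number of tested genes in brackets; red points had an adjusted p under 0.05 in camera with the preset correlation, none with an estimated one. The G2 and M phase list has the highest median (0.70) and the gastric chief cell list the lowest (-0.45).

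Lists of the Wnt pathway, stem cells and dysplasia held no gene past the threshold over all genes. Of 21 Wnt/beta-catenin target genes, 10 were above and 11 below 0, with a median of -0.09. Lgr5, a receptor of intestinal and gastric stem cells, averaged 126 ± 45.7 CPM in DP-DSCs and 142 ± 20.5 in TP-DSCs. Apcdd1, a Wnt inhibitor with the smallest p in the list, averaged 7.09 ± 6.97 CPM in DP-DSCs and 0.0205 ± 0.0354 in TP-DSCs, with 15.14 CPM in DP-DSCs replicate 3 and an edgeR adjusted p of 0.147 over all genes and 0.0981 over the list alone. Prox1 averaged 25.6 ± 4.99 and 45.0 ± 5.08, and Ephb3 60.04 ± 7.01 and 42.1 ± 8.17. Among 36 Wnt pathway components the median was -0.09, and 3 genes passed adjusted over the list alone, Wnt5b, Fzd9 and Tcf7l1. All had no reads in any TP-DSC library and stood at 0.885, 2.84 and 3.52 CPM in DP-DSCs. Absence was common at such abundance. Among all genes of 2 to 4 CPM in DP-DSCs, 48.0, 57.4 and 61.9% had no reads in TP-DSCs replicates 1, 2 and 3. The 23 gastrointestinal stem and progenitor markers had a median of -0.14, with Sox9 at 95.9 ± 30.2 and 68.0 ± 29.4 CPM and Ly6a (Sca-1) at 926 ± 162 and 1106 ± 125 CPM. The 17 markers of spasmolytic polypeptide-expressing metaplasia had a median of -0.145, and Clu (clusterin) was among the most abundant at 8049 ± 2980 and 5593 ± 1478 CPM. The 31 dysplasia and carcinoma associated epithelial genes had a median of -0.09, with 10 above and 21 below 0. Camera's direction is relative to the other tested genes, many of them without reads in TP-DSCs, so an upward direction need not mean higher in TP-DSCs. The medians and the sign of camera's test differed for the Wnt target, stem and progenitor, dysplasia, p53 target, TGF-beta and BMP, and detoxification lists. For these the camera direction was upward against a median below 0. The tuft cell list had a median of 0.23 against a downward camera direction. The RAS and MAPK and the ribosomal protein lists had means below 0 (-0.19 and -0.06) against medians above 0 and an upward camera direction, and the parietal cell list a mean of 0.03 against a median of -0.44.

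Signalling lists gave medians between -0.10 and 0.19, none of which passed. The 25 RAS and MAPK output genes had a median of 0.165 and 17 members above 0. The immediate early gene Egr1 averaged 124 ± 48.2 CPM in DP-DSCs and 228 ± 47.0 in TP-DSCs. The 22 YAP and TEAD target genes had a median of 0.19, with Cyr61 at 107 ± 40.4 and 175 ± 67.3 CPM. The 28 immediate early and dissociation stress genes had a median of 0.15 and 20 members above 0, with Fos at 306 ± 216 and 664 ± 414 CPM. The 18 Notch genes had a median of -0.07, the 30 TGF-beta and BMP genes of -0.10 and the 18 NF-kB and chemokine genes of -0.10. Tgfb3 averaged 53.8 ± 12.05 CPM in DP-DSCs and 105 ± 25.6 in TP-DSCs, and Nfkbiz 38.5 ± 8.03 and 65.6 ± 4.27 CPM. The 29 p53 target genes had a median of -0.02. In submission 4140 alone the medians of the RAS and MAPK and the YAP and TEAD lists lay below 0 (-0.04 and -0.03), against 0.215 and 0.22 in submission 3840. None of the members of these lists passed over all genes or adjusted over the list alone.

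Antigen presentation genes held 8 of 11 tested members below 0, with a median of -0.12 (camera adjusted p = 0.149). Adjusted over the list alone, 2 passed, Tapbp and H2-DMa, the latter at 0.542 CPM in DP-DSCs and without reads in TP-DSCs. Even among all genes of 1 to 2 CPM in DP-DSCs, 72.8, 78.6 and 76.0% had no reads in TP-DSCs replicates 1, 2 and 3. H2-T23, a non-classical class I gene, averaged 57.5 ± 6.21 CPM in DP-DSCs and 27.3 ± 13.5 in TP-DSCs, while the classical class I gene H2-K1 averaged 350 ± 84.7 and 323 ± 102. The 16 interferon-stimulated genes had a median of -0.22. The median difference of the antigen presentation list was -0.52 in submission 3840 and -0.81 in submission 4140. These are differences of mean log2 CPM, in which libraries with few or no reads weigh more than in edgeR's fold change. They are therefore not on one scale with the median of -0.12.

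Housekeeping and metabolic lists lay close to 0. The medians were 0.04 for 71 ribosomal protein genes, 0.075 for 55 nuclear genes of oxidative phosphorylation, 0.05 for 24 cholesterol synthesis genes, 0.02 for 32 amino acid and integrated stress response genes, 0.12 for 23 unfolded protein response genes and -0.12 for 31 drug and aldehyde detoxification genes. In submission 4140 the ribosomal, oxidative phosphorylation and cholesterol medians were -0.05, -0.04 and -0.07, against 0.16, 0.19 and 0.11 in submission 3840. Manf, an endoplasmic reticulum stress protein, averaged 158 ± 1.39 CPM in DP-DSCs and 219 ± 23.9 in TP-DSCs, and the cholesterol synthesis gene Idi1 80.9 ± 2.501 and 114 ± 11.6 CPM. None of the members of these lists passed over all genes or adjusted over the list alone. The list of mitochondrially encoded genes held no gene with a row in the files.

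Genes of other cell types were scarce in both groups. The summed CPM of 17 immune markers was 22.5 ± 22.7 in DP-DSCs and 7.29 ± 8.95 in TP-DSCs, nearly all of it Cd68. The 12 fibroblast markers summed to 2.31 ± 1.57 and 4.64 ± 3.21 CPM, with Col1a1 at 1.61 ± 0.974 and 0.0134 ± 0.0231 CPM, and the erythroid markers had no reads. The 9 smooth muscle markers summed to 17.7 ± 11.3 and 30.0 ± 35.6 CPM, mostly Mylk, and the 10 endothelial markers to 17.6 ± 13.9 and 10.2 ± 1.52 CPM, mostly Flt1. The fibroblast and the endothelial list each held only 2 tested genes. Adjusted over the list alone, 1 fibroblast gene (Col1a1) and 1 endothelial gene (Vwf) passed on the lower side. The other tested fibroblast gene, Pdgfra, had a log2 fold change of 2.19 ± 2.15 (SE). Vwf stood at 1.24 CPM in DP-DSCs and had no reads in TP-DSCs. At the abundance of Col1a1 and Vwf in DP-DSCs, most genes had no reads in each TP-DSC library.

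Genes of differentiated gastric and intestinal cells were present at uneven levels between libraries, and for some lists the levels followed the submission. The median deviation of the surface mucous list was 1.753 and 1.405 in DP-DSCs and TP-DSCs replicate 1 (submission 3840) and between -0.705 and -0.2 in the 4 libraries of submission 4140. The chief cell list stood at 0.989 and 0.559 against -0.638 to 0.102, and the metaplasia list at 1.05 and 0.646 against -0.537 to -0.064, in the same order. DP-DSCs replicate 1, highest for these lists, was lowest for the S phase (-0.919) and the G2 and M phase list (-0.863). Surface mucous cell markers summed to 1409 ± 401 CPM in DP-DSCs and 1303 ± 370 in TP-DSCs, led by Foxq1, Muc1 and Ctse. Chief cell markers summed to 1971 ± 193 and 1460 ± 262 CPM, nearly all from the broadly expressed genes Ctsd and Xbp1, and parietal cell markers to 748 ± 94.5 and 597 ± 111 CPM, led by Kcnq1 and Slc4a2. Intestinal differentiation markers summed to 808 ± 614 and 697 ± 342 CPM. Vil1 (villin) among them averaged 251 ± 5.22 and 274 ± 14.9 CPM, whereas Anpep ranged from 0 to 753 CPM over the libraries. Enteroendocrine markers summed to 75.2 ± 47.1 and 53.6 ± 34.7 CPM, tuft cell markers to 139 ± 63.1 and 158 ± 47.1 CPM, and squamous and basal markers to 1090 ± 413 and 987 ± 448 CPM, mostly Ly6d. Adjusted over the list alone, the intestinal markers Fabp2 and Cdh17, the tuft cell transcription factor Pou2f3 and the mesenchymal transition gene Zeb1 passed on the lower side. Each was under 2 CPM in DP-DSCs and without reads in TP-DSCs. Among all genes of 1 to 2 CPM in DP-DSCs, 72.8, 78.6 and 76.0% had no reads in TP-DSCs replicates 1, 2 and 3. The 11 tested genes of epithelial to mesenchymal transition had a median of -0.265.

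**Figure D4:**
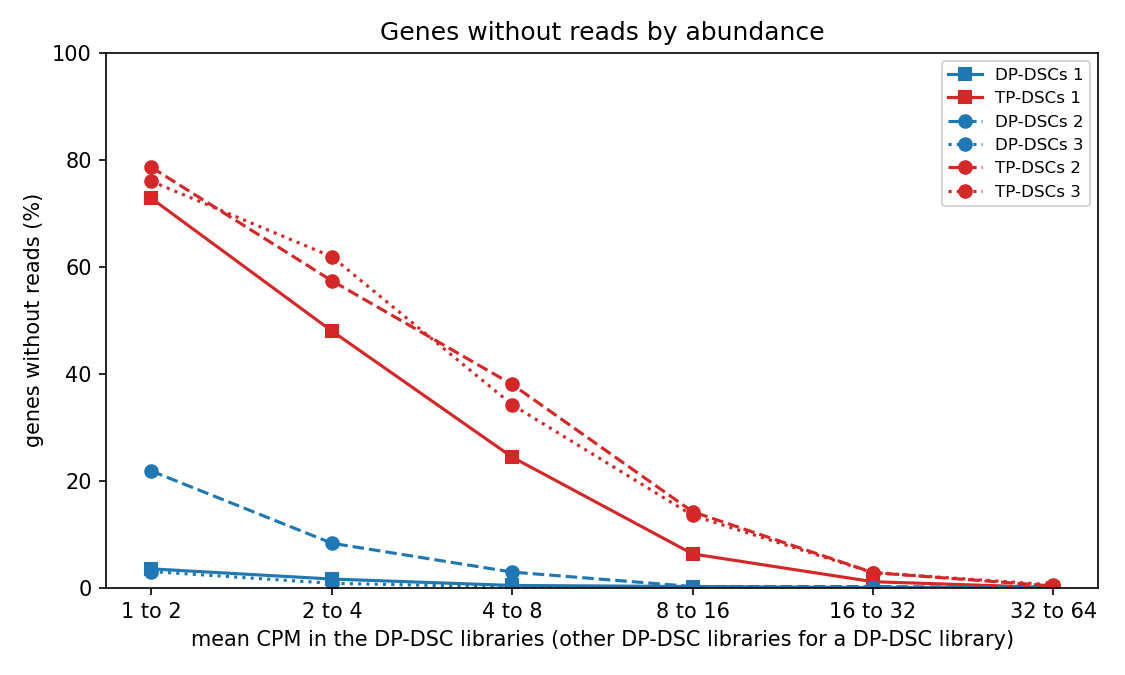
Percent of genes without reads in each library, by the mean CPM of the gene in the DP-DSC libraries (in the other DP-DSC libraries for a DP-DSC library). Among genes of 8 to 16 CPM, 6.3, 14.2 and 13.5% had no reads in TP-DSCs replicates 1, 2 and 3, against 0.2, 0.2 and 0.1% in DP-DSCs replicates 1, 2 and 3.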

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

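Tests of the loss of transcripts, of dividing cells and of other splits of the libraries for gene counts were chosen after the result was seen; the other tests of this part were set before.

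Reads that fell in no gene were not used in any comparison. Their share averaged 18.6 ± 2.12% (SD, n = 3) in TP-DSCs and 14.9 ± 0.681% (SD, n = 3) in DP-DSCs. Each TP-DSC library lay above each DP-DSC library (exact two-sided permutation test, p = 0.1, the smallest p that 3 against 3 libraries allow). It is listed because it is a signal outside the gene counts.

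The G2 and M phase list had a median log2 fold change of 0.704, but the groups overlapped across submissions (0.154 in DP-DSCs replicate 2 and -0.001 in TP-DSCs replicate 1). They did not overlap within submission 4140, which held only 2 libraries of each group. In edgeR 0 members passed over all genes. Camera's call was lost with an estimated correlation (adjusted p = 0.904) and in fry (adjusted p = 0.367). Random lists matched on expression, transcript length and GC content had medians between -0.128 and 0.150 in their central 95%, which argues against transcript length and GC bias. Loss of transcripts is also argued against, though the list and its median were the same as in the test of length and GC bias. All 36 members had reads in all 6 libraries, and random lists of such genes stayed between -0.136 and 0.166. A larger share of dividing cells in the TP-DSC sort may account for it. The S phase list, which shares no gene with it, had a median of 0.498 against at most 0.130 in the central 95% of matched lists. That median was 0.190 without DP-DSCs replicate 1 and 0.065 in submission 4140 alone. The matched lists draw genes independently and so leave out that the genes of a list vary together. With the correlation estimated, the S phase list did not pass in camera (unadjusted p = 0.259, adjusted p = 0.904). It did not pass in fry either (adjusted p = 0.724). Whether the libraries fell this way by chance stays open: 10 splits are too few for a share under 0.05, 2 of them, the real one included, gave a median as large, and the highest other was 0.829, for the split that sets both libraries of submission 3840 with DP-DSCs replicate 3 (within the submissions the medians were 0.849 and 0.665).

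Genes without reads in all 3 TP-DSC libraries numbered 434 of 11763 genes with at least 1 CPM in DP-DSCs. If each library lost genes independently at its own rate for their abundance, 410.1 would be expected (95% of simulations between 378 and 442). The observed count was 1.06 times the expected one, which argues against genes switched off in TP-DSCs as the main source. These rates come from the same TP-DSC libraries, so switched-off genes would raise the expected count as well. A smaller share of switched-off genes could therefore go unseen. Few captured molecules in these libraries could explain the pattern: only 19.4% of the 2236 genes without reads in at least 1 TP-DSC library were without reads in all 3, and the share fell with abundance in each. Among 9711 genes of at least 8 CPM, 4 were without reads in all 3 (Pcyt1b, Abtb1, Megf6 and Lysmd4) where 2.6 were expected, so for single genes a true loss stays open.

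For gene counts, 10 of the 10 splits of the 6 libraries gave as many calls in edgeR as the real one, since both the real count and the highest other were 0 (DESeq2 called 278 genes for the real split). At an unadjusted p under 0.05, 3 of the 10 splits, the real one included, gave as many genes; the real count was 728 and the highest other 939, for the same split that sets both libraries of submission 3840 with DP-DSCs replicate 3. Both splits above the real one (939 and 856) put the 2 libraries of submission 3840 on one side. Among the 6 splits that keep 1 library of submission 3840 on each side, the real one was highest, with 728 genes against at most 233 and a G2 and M phase median of 0.704 against at most 0.434. The real split also sets the 3 libraries with the fewest genes with reads against the other 3. Of its 728 genes, 387 had no reads in any TP-DSC library, so its rank by gene count cannot be told apart from this. Either set of splits is too small for a share under 0.05.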

How the results depend on the processing

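Restricting to genes with reads in all 6 libraries and removing the GC and length trend were chosen after seeing the data. The count of genes called by edgeR was 0 under every scaling, filter, block and left-out library that was run, and with limma-voom. DESeq2 called 278 genes and, with the submission number as a block, 313 genes; in submission 4140 alone DESeq2 called 275 genes. DESeq2 differs from edgeR in its estimate of the spread, size factors, tested genes and filtering together, and which of these makes the difference was not tested; on simulated counts DESeq2 made 95.2 false calls against 2.4 for edgeR. The edgeR count at an unadjusted p under 0.05 ran from 363 (reads in all 6 libraries) to 1811 (without TP-DSCs replicate 1). The 363 genes were of 9524 tested, a share under 0.05. Of the sort and epithelial surface markers, 1 passed in DESeq2 with the submission number as a block, and 0 otherwise. The number of lists past 0.05 was 3 with the preset correlation, 9 with no filter, 6 with the GC and length trend removed, and 0 with an estimated correlation, with fry, and with an estimated correlation over genes with reads in all 6 libraries; the cause was not tested. Leaving out 1 library gave 3 to 11 lists: 7 without DP-DSCs replicate 1, 6 without DP-DSCs replicate 3, 6 without TP-DSCs replicate 2 and 11 without TP-DSCs replicate 3. The medians do not depend on the correlation, so with an estimated correlation or fry they stayed at 0.704 for the G2 and M phase list, 0.498 for the S phase list and 0.126 for the hypoxia list while the calls were lost. The G2 and M phase median ran from 0.478 to 0.969 with 1 library left out, with camera's call at the preset correlation kept each time. The S phase median fell to 0.065 in submission 4140 alone, where its call was lost (adjusted p = 0.0744), and ran from 0.190 to 0.670 with 1 library left out. The hypoxia and glycolysis median ran from -0.220 to 0.393 with 1 library left out, and changed sign without DP-DSCs replicate 2 (-0.220) and without TP-DSCs replicate 1 (-0.039), where its camera call was also lost (adjusted p = 0.517 and 0.132; over all alternatives from 1.607e-06 to 0.937). Of 2777 values of the 157 named genes under the alternatives, 2740 kept their direction and 37 changed it, none of these past the threshold, and 58 passed the threshold, all in DESeq2 with or without the block. Requiring a log2 fold change of at least 1 leaves 0 genes by construction. No paired analysis was possible because the replicate numbers follow the order of deposit; with the submission number as a block, edgeR called 0 genes, with 843 at an unadjusted p under 0.05. The median of genes with reads in all 6 libraries was 0.011 in the reported fit and stayed between -0.034 and 0.069. Among genes of 8 to 16 CPM in DP-DSCs, 6.3, 14.2 and 13.5% had no reads in TP-DSCs replicates 1, 2 and 3, which limits what can be said of less abundant genes.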

Other observations

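The list of lysosomal genes was made after the data were seen, and its tests were chosen then; the test of chromosomes was set before.

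Propionyl-CoA carboxylase is built from alpha and beta subunits encoded by Pcca and Pccb, and these lay on opposite sides of 0. Pcca had a log2 fold change of 0.90 ± 0.23 (SE), with differences of 0.79 in submission 3840 and 0.96 in submission 4140. Pccb had -1.22 ± 0.30, with differences of -1.41 and -1.11. Neither passed in edgeR (adjusted p = 0.177 and 0.136), both kept their direction under all 18 alternatives, and both passed in DESeq2 (adjusted p = 0.00744 and 0.000346). Over the alternatives the adjusted p of Pcca ran from 0.00744 to 0.998 and that of Pccb from 0.000346 to 0.998. The pair was picked from the smallest p-values, so the opposite signs are a value to follow up and were not tested as a difference.

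Several lysosomal genes, Ctsb and Pld3 among them, stood among the lower genes when the results were first read. The same 6 libraries were then used for a list of 46 other lysosomal genes, which included Ctsd, also a member of the chief cell list. This comparison is therefore not independent of the first reading. Of the 46 genes, 38 had a log2 fold change below 0 and 8 above, with 0 past the threshold in edgeR. Lamp1, a membrane protein of lysosomes, averaged 783 ± 58.2 CPM in DP-DSCs and 569 ± 81.2 in TP-DSCs, the cathepsin Ctsd 1377 ± 83.6 and 1020 ± 123, and the saposin precursor Psap 864 ± 78.4 and 646 ± 58.9. The median was -0.27, with -0.218 in submission 3840 and -0.303 in submission 4140, and random lists matched on expression, transcript length and GC content stayed between -0.153 and 0.055 in their central 95%. A lower level of lysosomal genes in TP-DSCs is thus a hypothesis that the median is consistent with. Camera gave it less: p = 0.0597 with the preset correlation and p = 0.276 with an estimated one, and removing the GC and length trend brought the median to -0.162. Over the alternatives the median ran from -0.332 to -0.162 and the preset-correlation p from 0.000163 (reads in all 6 libraries, where p = 0.0689 with an estimated correlation) to 0.552 (without TP-DSCs replicate 3, median -0.208). In the splits of the 6 libraries, 1 of 10, the real one, gave a median as large; the real size was 0.27 and the highest other 0.245 (0.111 among the splits that keep 1 library of submission 3840 on each side), and 10 splits are too few for a share under 0.05.

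A gain or loss of a chromosome in one sorted population was tested on 9474 genes with reads in all 6 libraries. Over 20 chromosomes with at least 100 genes, the median log2 fold change ran from -0.05 (chromosome 19) to 0.069 (chromosome X), and 0 chromosomes lay beyond the range of random gene sets. A shift of 0.2 or more, set as the bound beforehand, was seen on no chromosome. This argues against a whole-chromosome change in most cells of one population and not the other. A change shared by both populations would not show in this comparison.

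The 45S ribosomal RNA gene Rn45s stood at 1512 CPM in DP-DSCs replicate 1 and between 9063 and 13587 CPM in the other 5 libraries. TP-DSCs replicate 1, from the same submission, stood at 9961 CPM.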
